A study of Mus musculus with 14 samples.

How the data were processed

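Polyadenylated RNA was sequenced from 14 mouse libraries, as single-end reads of 75 nucleotides on a NextSeq 500. Of these, 6 came from liver tissue of mice that had been injected with the liver carcinogen diethylnitrosamine (DEN) and fed a high-fat diet, 3 of them wild type (WT) and 3 without p62 (p62KO). The other 8 came from hepatic stellate cells (HSC), the fibroblast-like cells of the liver that can turn into matrix-producing myofibroblasts. These cells had been taken from WT or p62KO livers, immortalized with the SV40 T antigen and cultured with vehicle or with calcipotriol, an agonist of the vitamin D receptor, giving 4 groups of 2 libraries. The time of exposure to calcipotriol and the number of independent cell lines or cultures were not given in the sources used here.

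The deposited tables held whole-number counts per gene symbol, 1 column per library, in 23420 lines each. The name of the stellate cell table speaks of another unit, but its values were whole, their totals differed between libraries, and they had not been divided by size factors, so they were read as raw counts. The submitters' processing notes name the genome build mm10. The aligner, the counting tool and the annotation were not given in the sources used here. A spreadsheet had turned 27 symbols into dates, and these were kept under the date but never named. Positions on GRCm38 were found for 98.1% of the symbols through the reference annotation. The tables held no mitochondrially encoded genes. Of 736 members of the 36 fixed gene lists, 4 were found under an older symbol and 19 were not in the tables.

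Total counts per library ranged from 17506607 to 20040583 in liver and from 15207117 to 29079258 in stellate cells. A gene listed at 0 is therefore known only to lie under a limit, which was set at 3 counts over the group. Where every library of a group was at 0, the fold is given as a lower bound against that limit, and where a group held 1 to 3 counts, the ratio is given with its 95% counting interval. Such intervals and limits cover counting error only, because reads without molecular identifiers are not independent molecules.

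Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) after TMM scaling and the filterByExpr filter. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. All tests were two-sided, except a permutation test of chromosome 10 that counted only medians as low as the observed one. The 6 liver libraries made 1 fit and the 8 stellate cell libraries another, so that the 4 groups of 2 shared an estimate of the spread. The comparisons were p62KO against WT in liver, in vehicle-treated and in calcipotriol-treated stellate cells, calcipotriol against vehicle in each genotype, and the difference between these responses (the interaction of treatment and genotype). Overlap between liver and stellate cells was tested with Fisher's exact test over the genes tested in both. Levels are given as CPM, the usual counts relative to the scaled library total, as mean and SD. Changes are given as log2 fold change with an approximate standard error (SE). This SE is the size of the change divided by the square root of the test's F statistic.

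The gene lists, with at least 5 tested members, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. They were tested again with a correlation estimated from the data. That run also rests on the few residual degrees of freedom of each fit, which the preset run does not. A list can therefore lose its call there even where its genes are not correlated. The lists were also tested with fry, which asks whether their genes moved on balance in 1 direction without comparing them with other genes. Members were also adjusted over the list alone.

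Genes were named by a rule. Sqstm1, Vdr and Cyp24a1 were always named. In each comparison, the 8 genes with the largest rise and the 8 with the largest fall were eligible among those that passed, had a mean of at least 5 CPM in the higher group, had every library of 1 group above every library of the other, and were not unnamed gene models. From each list that was called or had at least 3 passing members, the 3 passing members with the smallest p were eligible. From a called list with no passing member, the 2 members with the smallest p were eligible, as values that did not pass, and from any other list the 1 member with the smallest p. Where no gene passed, the 5 with the smallest p in each direction were eligible, as values that did not pass. Any other gene that is named was chosen after its values were seen, and the text says so. Of the genes eligible by this rule, 1 is not reported here, though the counts include it. The groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined.

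The alternatives were the DESeq2 1.42.0 Wald test, RLE size factors, no filter, a filter at 5 CPM, the replicate number as a block, a minimum fold of 2, each library left out in turn, and for stellate cells a fit of only the 2 groups compared. Leaving out a library of a pair leaves a lone library, which is then assumed to vary like the other groups. Replicate numbers were not treated as pairs. Across genes, which are not independent replicates, the residuals of libraries with the same number correlated at r = 0.192, -0.191 and 0.142 in liver, and between -0.148 and 0.0367 in stellate cells, except for r = 0.433 between calcipotriol-treated WT and vehicle-treated p62KO libraries. Alternatives chosen after seeing the data left out a pair of stellate cell libraries that stood apart, removed the median shift of each chromosome, exchanged the replicate numbers of a pair in the block, and repeated the list tests with libraries left out. The edgeR gene test, for genes that had passed the filter, was tried on simulated data made from the same tables. The list tests were not tried. Each simulated gene had the same spread in every library, and no chromosome or library was shifted as a whole. The numbers recovered and wrongly called therefore do not cover such shifts. Among 100 genes changed 4-fold per comparison, between 54 (the interaction) and 93 (liver) were recovered, and among 100 changed 2-fold, between 4 and 42, with at most 9 unchanged genes called. Every column of counts in the tables was used.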

Results

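Gene expression was measured in 14 mouse libraries. Livers of mice given DEN and a high-fat diet made up 6 of them, 3 WT and 3 p62KO. The WT livers held 20040583, 17987624 and 19841665 counts and the p62KO livers 19155935, 19367998 and 17506607. Immortalized hepatic stellate cells made up the other 8, with 2 libraries in each of 4 groups. The WT libraries held 15207117 and 15362210 counts with vehicle and 16566069 and 18613062 with calcipotriol, and the p62KO libraries 18179803 and 18938666 with vehicle and 26159634 and 29079258 with calcipotriol. The series asks what p62, the autophagy receptor encoded by Sqstm1, does in stellate cells, fibrosis and liver cancer, and how it relates to the vitamin D receptor. Nothing in the labels says that replicates came from separate cultures or cell isolations, so in stellate cells the p-values and SDs measure only the spread between libraries. Nor do the labels say how many cell lines stand behind each genotype, so every difference given between p62KO and WT stellate cells is a difference between the lines used, whether or not it comes from the loss of p62. The vehicle-treated WT libraries differed by little more than counting error (chi-squared per degree of freedom 1.66), against 12.2 for calcipotriol-treated WT, 61 for vehicle-treated p62KO and 200 for calcipotriol-treated p62KO libraries.

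Sqstm1 (mm10 chromosome 11, 50199366 to 50210827) was nearly absent in every p62KO library. In liver it stood at 578, 448 and 583 CPM in the WT animals and at 1.56, 2.12 and 1.44 CPM in the p62KO animals. In stellate cells it stood at 318 and 316 CPM in vehicle-treated and 340 and 339 CPM in calcipotriol-treated WT libraries, against 0.835 and 0.211 CPM, and 0.265 and 0.608 CPM, in the matching p62KO libraries. Its log2 fold change was -8.29 ± 0.245 (SE) in p62KO liver, -9.22 ± 0.489 in vehicle-treated and -9.57 ± 0.489 in calcipotriol-treated p62KO stellate cells, and it passed the test in all 3 comparisons.

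**Figure D1:**
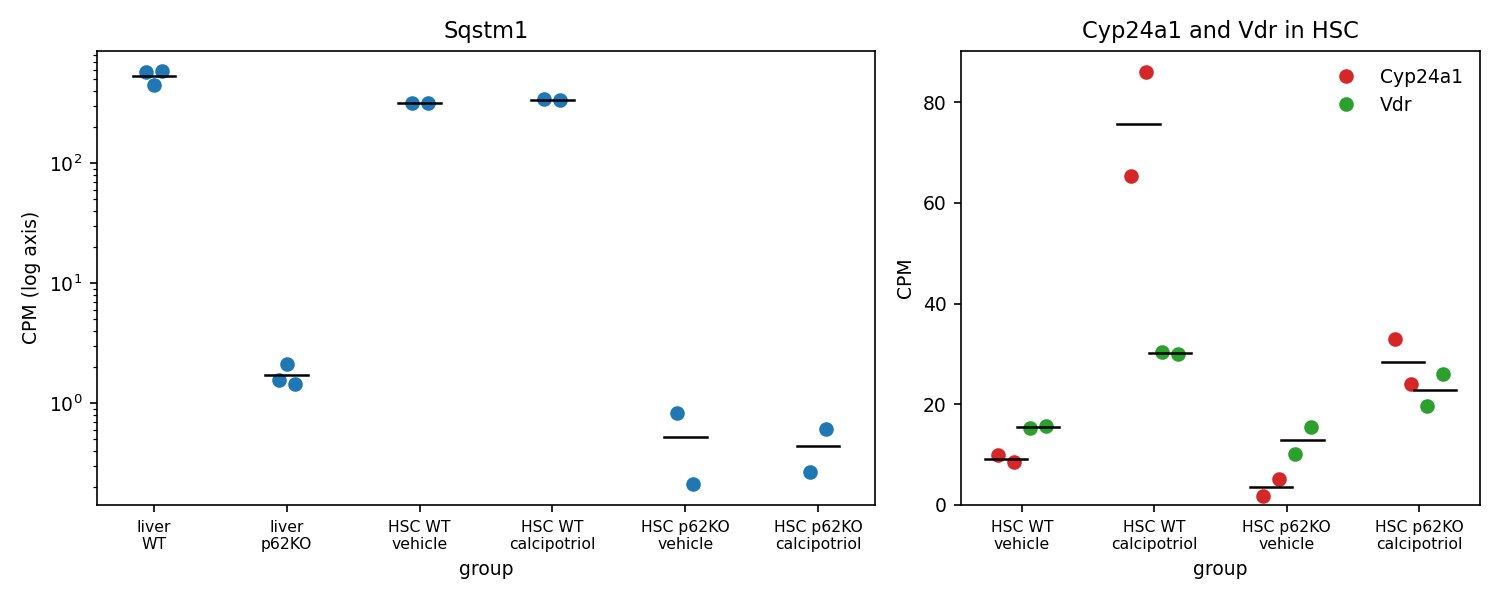
Levels of Sqstm1 in all 14 libraries (left, CPM on a log axis) and of Cyp24a1 and Vdr in the 8 stellate cell libraries (right, CPM), by group; each point is a library and each bar a group mean. No p62KO library exceeded 2.12 CPM of Sqstm1, and Cyp24a1 was higher with calcipotriol than with vehicle in both genotypes, a difference that did not pass the main test.

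The first comparison asked how livers without p62 differed after DEN and a high-fat diet. In the extracellular matrix, 16 of 27 tested members of the list of collagens and matrix rose, none fell, and 11 did not pass (25 rose when adjusted over the list alone; median log2 fold change 1.32). As a set the list gave a camera adjusted p of 6.15e-12, and an adjusted p of 0.388 with an estimated correlation. Lumican (Lum), a proteoglycan that binds collagen, rose from 11.4 ± 2.83 to 35.9 ± 1.11 CPM (SD, n = 3 each), and Sparc, a matrix glycoprotein, from 81.1 ± 8.38 to 342 ± 141 CPM. Sparc lies within 15 Mb of Sqstm1, on chromosome 11 at 55394500 to 55423183. Of the matrix remodelling list, 7 of 23 members rose (15 adjusted over the list alone), among them the collagen cross-linking enzymes Loxl1 (log2 fold change 1.39 ± 0.241, SE) and Loxl2 (1.52 ± 0.275) and the membrane-bound protease Mmp14 (1.13 ± 0.204). TGF-beta target genes rose in 7 of 24 cases (10 adjusted over the list alone), including Pmepa1 (1.00 ± 0.178) and the receptor gene Tgfbr2 (1.08 ± 0.21), and 3 of 18 contractile genes of myofibroblasts rose (6 over the list alone), namely Vim, Tagln2 and Tpm4.

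Many genes of dividing cells also rose in p62KO livers. Of the cell cycle list, 17 of 30 members rose and none fell (25 adjusted over the list alone; median 1.85; camera adjusted p = 5.52e-11, and adjusted p = 0.388 with an estimated correlation). Mki67, a marker of proliferation, rose from 1.90 ± 0.553 to 11.4 ± 3.13 CPM (SD, n = 3 each), and the topoisomerase gene Top2a from 1.24 ± 0.297 to 8.82 ± 4.35 CPM. Pttg1, which encodes securin and lies on chromosome 11 at 43420250 to 43426251, went against them and fell from 24.3 ± 3.70 to 2.58 ± 0.556 CPM. Markers of liver tumours and progenitors rose in 4 of 20 cases (13 over the list alone), among them Lcn2 (log2 fold change 1.64 ± 0.246), Ly6d (2.73 ± 0.458) and Spink3 (4.32 ± 0.848). Of the p53 targets, 3 of 19 rose, including Plk2 (1.14 ± 0.147) and Zmat3 (0.98 ± 0.214); adjusted over the list alone, 6 rose and 2 fell.

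Some markers of other cell types also rose. Macrophage markers rose in 7 of 22 cases (16 adjusted over the list alone; median 0.99; camera adjusted p = 3.49e-07, and adjusted p = 0.388 with an estimated correlation), led by the mannose receptor Mrc1 (0.90 ± 0.134), the lipopolysaccharide co-receptor Cd14 (1.29 ± 0.196) and Trem2, a receptor of lipid-laden macrophages (1.99 ± 0.309). Cholangiocyte markers rose in 4 of 13 cases (11 over the list alone; median 1.76), including Cldn4, Spp1 (osteopontin) and Cdh1. Among inflammatory cytokines and NF-kB targets, 3 of 22 rose (8 over the list alone): the adhesion molecule Vcam1 (1.51 ± 0.156), the macrophage growth factor Csf1 (0.66 ± 0.131) and the chemokine Ccl3 (2.31 ± 0.558). The medians of endothelial markers (0.33), T and NK cell markers (0.78) and quiescent stellate cell markers (0.24) were above 0, and these lists were not called (camera, adjusted p = 0.142, 0.107 and 0.169), with no member past the threshold.

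Some genes of hepatocytes, bile acids and detoxification fell, a minority of each list. Of the hepatocyte function list, 5 of 30 members fell and none rose (5 adjusted over the list alone; median -0.66; camera adjusted p = 0.000156, and adjusted p = 0.388 with an estimated correlation). They included Cyp7a1, the rate-limiting enzyme of bile acid synthesis, which fell from 169 ± 31.9 to 65.0 ± 6.83 CPM (SD, n = 3 each), Cyp8b1, which makes cholic acid, and the bile acid transporter Slc10a1. Of the bile acid and xenobiotic list, 5 of 20 fell (5 over the list alone), among them Nr1i3, the xenobiotic receptor CAR (log2 fold change -1.58 ± 0.194), and Cyp2a5 (-2.16 ± 0.286). Of the NRF2 targets, which respond to oxidative stress, 6 of 34 fell, including Gstm4 (-1.22 ± 0.157) and Abcc3 (-0.82 ± 0.145), and G6pdx rose (1.02 ± 0.176); over the list alone 7 fell and 1 rose. Of the circadian clock list, 2 of 18 fell (3 over the list alone), and these were Usp2 and Gm129 (also called Ciart).

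No member passed in 2 called lists. Of the genes of PPAR-alpha and fatty acid oxidation, 25 were tested (median -0.36), with Vnn1 at -0.51 ± 0.136 (adjusted p = 0.0571) and Ech1 at -0.64 ± 0.175 (adjusted p = 0.0621). Of the autophagy and lysosome genes, 28 were tested (median -0.18), with Atg7 at -0.49 ± 0.123 (adjusted p = 0.0529) and Gabarapl1 at -1.01 ± 0.256 (adjusted p = 0.0541); none passed in either list when adjusted over the list alone, and the adjusted p of both lists was 0.708 with an estimated correlation. The vitamin D receptor targets were called as higher (median 0.75; adjusted p = 0.388 with an estimated correlation), but the member that rose was Spp1, which is also a cholangiocyte marker, and 4 of 9 rose when adjusted over the list alone. Vdr and Cyp24a1 themselves had too few counts in liver to be tested.

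**Figure D2:**
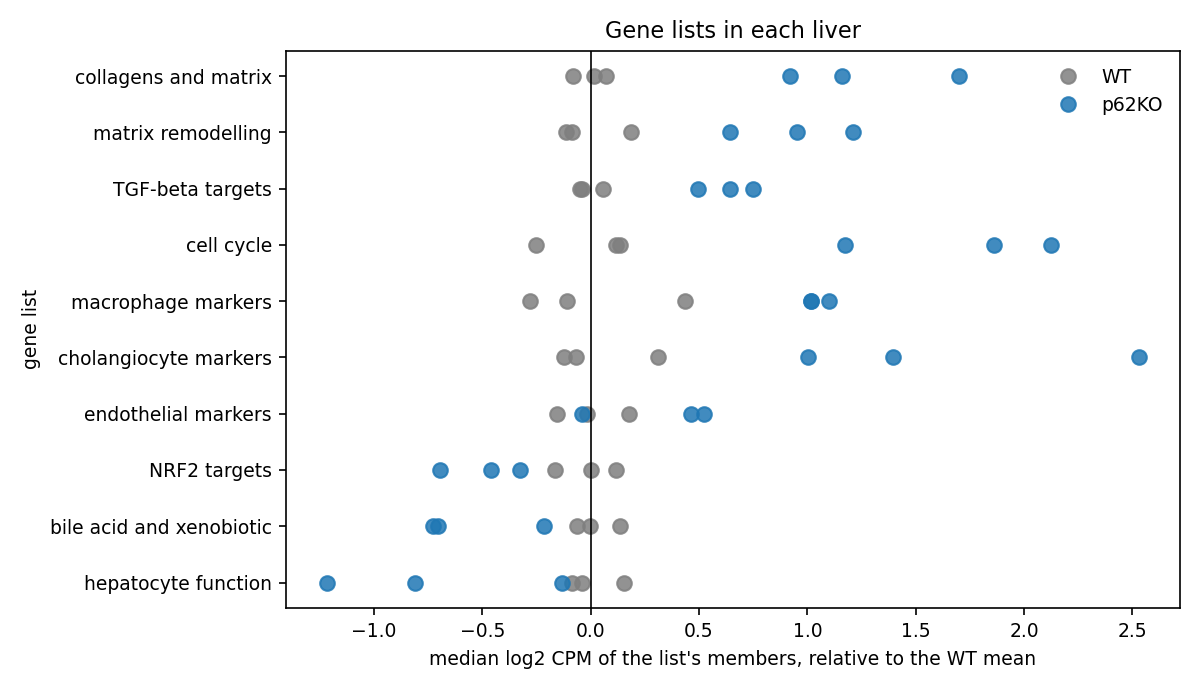
Median log2 CPM of the members of 10 gene lists in each of the 6 livers, relative to the WT mean; each point is a liver. The 3 p62KO livers lie between 0.92 and 1.70 for collagens and matrix, above all WT livers, while for hepatocyte function they lie at -1.22, -0.81 and -0.13.

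In all, 1020 of 12851 tested genes differed in liver, 576 higher and 444 lower in p62KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 462 of them by at least 2-fold, 370 higher and 92 lower. Camera called 17 of 32 lists, with adjusted p from 6.15e-12 (collagens and matrix) and 5.52e-11 (cell cycle) to 0.0287 (p53 targets). With an estimated correlation none of the 17 held (adjusted p = 0.388 for all except the lists of PPAR-alpha and of autophagy). Lists with an estimated correlation below the preset one were lost too, namely the circadian clock (-0.015) and vitamin D receptor targets (-0.12). The loss is therefore not a measure of correlation between genes alone. The count of genes rested on single livers: it was 12, 22 and 3 without WT replicates 1, 2 and 3, 110 and 9 without p62KO replicates 1 and 2, and 3669 without p62KO replicate 3, the p62KO liver nearest to WT, while the replicate block gave 639 and DESeq2 2442. Of 65 named genes that passed, Sqstm1 and Pttg1 passed in every one of these leave-one-out fits.

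The second comparison asked how stellate cells without p62 differed without calcipotriol. Contractile genes of myofibroblasts rose in 7 of 18 cases (8 adjusted over the list alone; median log2 fold change 0.82; camera adjusted p = 0.00702, and adjusted p = 0.805 with an estimated correlation), and none fell. Acta2, which encodes alpha smooth muscle actin, rose from 726 ± 18.9 to 2661 ± 41.2 CPM (SD, n = 2 each), Actg2 from 109 ± 2.91 to 608 ± 27.1 CPM and calponin (Cnn1) from 15.4 ± 1.59 to 286 ± 97.9 CPM. Genes of the unfolded protein and integrated stress response rose in 8 of 24 cases (9 over the list alone), including Herpud1 (log2 fold change 1.30 ± 0.167, SE), Mthfd2 (1.06 ± 0.187) and Sesn2 (1.23 ± 0.234). TGF-beta targets rose in 6 of 24 cases and fell in 1 (10 and 1 over the list alone), among them Bhlhe40 (2.37 ± 0.24), Tgfb2 (1.82 ± 0.329) and Pmepa1 (1.22 ± 0.24), and p53 targets rose in 7 of 19 and fell in 1 (10 and 2 over the list alone), among them the cell cycle inhibitor Cdkn1a (1.63 ± 0.294) and Perp (7.05 ± 0.749).

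Inflammatory genes rose in 6 of 21 cases (13 rose and 1 fell over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.931 with an estimated correlation), but mostly in 1 library. The chemokine Ccl2 stood at 350 CPM in p62KO vehicle replicate 1 and 25.9 CPM in replicate 2, against 8.56 and 7.63 CPM in WT. Saa3, a marker of acute phase responses named here after its values were seen, stood at 298 CPM in p62KO vehicle replicate 1 and at 0.158 CPM in replicate 2. A split between replicates was also seen in WT cells with calcipotriol. There Saa3 stood at 30.7 and 0.544 CPM and Ccl2 at 26.7 and 6.32 CPM in replicates 1 and 2. The inflammatory list median in p62KO vehicle replicates 1 and 2 was 2.08 and 0.38 above vehicle-treated WT (log2). Cholesterol synthesis genes were called as higher by camera (adjusted p = 0.0277, and adjusted p = 0.931 with an estimated correlation), with 1 of 22 past the threshold, Fdps (1.51 ± 0.401), and 0 over the list alone; their median stood at 0.98 in p62KO vehicle replicate 1 and 0.19 in replicate 2. Of the lists that were not called, that of collagens and matrix held 7 genes that rose and 5 that fell: Col1a2, a chain of type I collagen, rose (1.66 ± 0.192) and Thbs2 fell (-4.68 ± 0.373). The NRF2 targets held 4 that rose, among them Nqo1 (2.06 ± 0.327) and the cystine transporter Slc7a11 (2.12 ± 0.384), and 1 that fell, Txnrd1 (-1.37 ± 0.202).

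Some genes were near absent from 1 genotype. Thy1, a surface marker of portal fibroblasts, stood at 225 ± 73.9 CPM (SD, n = 2) in p62KO and 0.0340 ± 0.0480 CPM in WT, a ratio of 6670 (95% counting interval 1200 to 264000), and the proteoglycan Cspg4, a pericyte marker, differed by a ratio of 846 (234 to 6990). The lipase gene Mgll was at least 425-fold higher and Cthrc1 at least 151-fold higher in p62KO, with no counts in WT. The homeobox gene Barx1 was at least 181-fold lower, with no counts in p62KO, and the transcription factor gene Ebf3 fell from 41.1 ± 0.941 to 0.157 ± 0.222 CPM.

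The medians of some chromosomes differed between p62KO and WT stellate cells. Of 626 tested genes on chromosome 10, 176 fell and 21 rose (31.5% of them), and their median log2 fold change was -0.64, the most extreme apart from the 4 tested genes of Y (-0.98). The median was 0.43 on chromosome 3 (110 rose and 15 fell), 0.43 on 13 (64 and 13), 0.37 on 6 (79 and 17) and 0.35 on 4 (111 and 16), and -0.36 on chromosome 5 (23 rose and 111 fell). Relative to vehicle-treated WT cells, the chromosome 10 median was -0.59 and -0.67 in the vehicle-treated and -0.70 and -0.72 in the calcipotriol-treated p62KO libraries, while in p62KO liver the median change was 0.01. In livers, the chromosome medians apart from Y lay between -0.03 and 0.08.

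**Figure D3:**
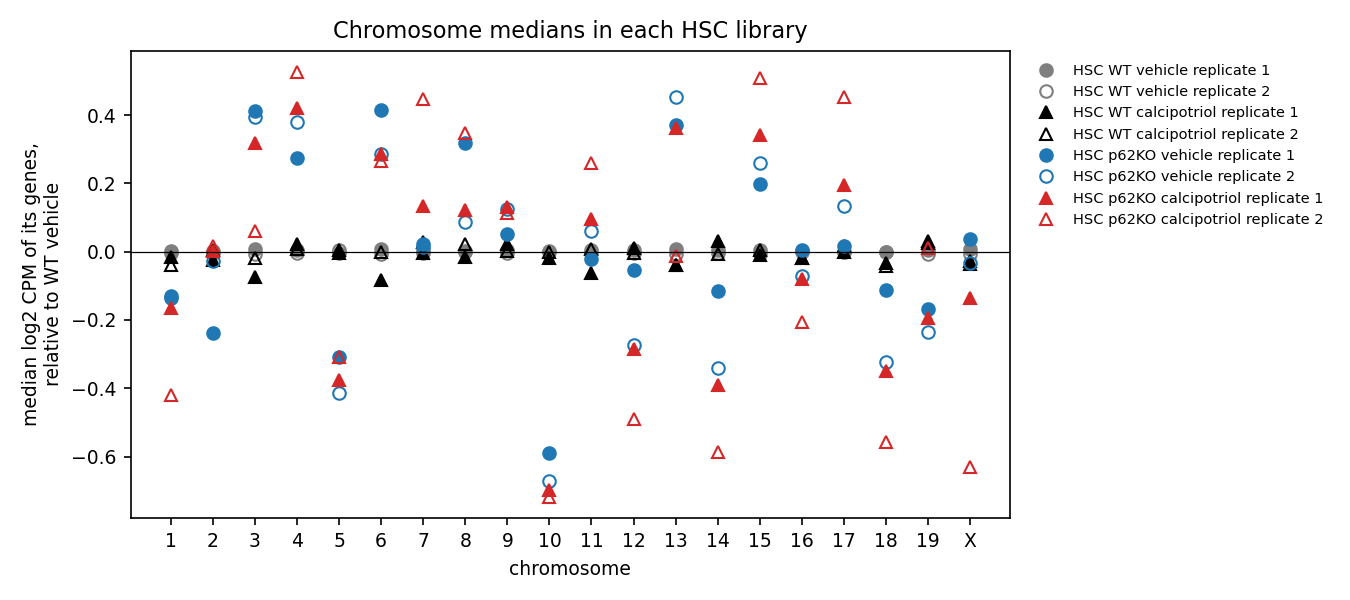
Median log2 CPM of the genes of each chromosome in each of the 8 stellate cell libraries, relative to the mean of the vehicle-treated WT libraries; each point is a library and colours and shapes mark group and replicate. The 4 p62KO libraries lie between -0.72 and -0.59 on chromosome 10, while WT libraries stay near 0, and p62KO calcipotriol replicate 2 lies lowest on X.

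In all, 1634 of 12681 tested genes differed, 881 higher and 753 lower in p62KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1173 of them by at least 2-fold. Camera called 6 of 27 lists (adjusted p from 0.00702 for contractile genes to 0.0387 for TGF-beta targets), and with an estimated correlation none held (adjusted p = 0.805 or 0.931). The count was 243 and 238 without WT vehicle replicates 1 and 2, 872 and 873 without WT calcipotriol replicates 1 and 2, 841 without p62KO vehicle replicate 1, 3625 and 3635 without p62KO calcipotriol replicates 1 and 2, 5459 without both p62KO vehicle replicate 1 and p62KO calcipotriol replicate 2, and 1002 with chromosome medians removed (895 of them shared). Without p62KO vehicle replicate 1, 3 lists were called, of which the contractile and the unfolded protein lists were shared, and without replicate 2, 11 were called. TGF-beta targets were lost without WT vehicle replicate 1, without either WT calcipotriol library, and without p62KO calcipotriol replicate 2. Cholesterol synthesis was lost without WT vehicle replicate 1 or p62KO calcipotriol replicate 2. In all, 28 of 66 named genes passed in every leave-one-out fit, among them Actg2, Cnn1, Col1a2, Thbs2, Thy1 and Barx1.

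The third comparison asked how p62KO and WT stellate cells differed with calcipotriol. Contractile genes rose in 8 of 18 cases (11 adjusted over the list alone; median 0.82), among them Actg2 (2.72 ± 0.223), Cnn1 (3.59 ± 0.379) and Tagln (2.07 ± 0.262). Of the unfolded protein and integrated stress response genes, 11 of 24 rose and 2 fell (11 and 3 over the list alone), with Chac1 (2.33 ± 0.322) and the serine synthesis enzyme Phgdh (1.90 ± 0.262) among those that rose. Lists that were not called held Inhba, a TGF-beta family ligand (1.74 ± 0.204), the interferon-induced gene Ifit2 (-1.81 ± 0.318) and Hgf, the hepatocyte growth factor (-5.71 ± 0.87). Thy1 again stood at 352 ± 92.2 CPM (SD, n = 2) in p62KO against 0.0559 ± 0.00212 CPM in WT, and Barx1 was at least 262-fold lower. The test gave 1300 genes higher and 1209 lower in p62KO, 2509 of 12681 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05).

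Camera called the contractile and the unfolded protein lists (adjusted p = 0.00217 for each), and neither held with an estimated correlation (adjusted p = 0.598). The count was 1127 and 1165 without WT vehicle replicates 1 and 2, 346 and 272 without WT calcipotriol replicates 1 and 2, 6052 without p62KO calcipotriol replicate 1, 5606 without both libraries that stood apart, 1644 at a minimum of 2-fold, 1293 in a fit of only the 2 groups, and 1417 with chromosome medians removed. Without p62KO calcipotriol replicate 1, the unfolded protein list was no longer called. Without each WT vehicle library or p62KO vehicle replicate 2, 4 lists were called, without WT calcipotriol replicate 2, 6, and without p62KO vehicle replicate 1, 7, always with the same 2 among them. Of 83 named genes that passed, 32 passed in every leave-one-out fit. The Y-linked gene Ddx3y, named here after its values were seen, stood at 43.1 and 11.5 CPM in p62KO calcipotriol replicates 1 and 2, against 112 and 115 CPM in the calcipotriol-treated WT libraries.

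Calcipotriol was compared with vehicle in WT stellate cells to ask what the vitamin D receptor agonist did where p62 was present. Cyp24a1 (chromosome 2, 170482708 to 170497145), which breaks down active vitamin D and is the classical target of its receptor, stood at 75.7 ± 14.6 CPM (SD, n = 2) with calcipotriol and 9.18 ± 0.951 CPM with vehicle, a log2 fold change of 3.04 ± 0.416 (SE) that did not pass (adjusted p = 0.242). Vdr stood at 30.2 ± 0.194 CPM against 15.4 ± 0.225 CPM (0.97 ± 0.254, adjusted p = 1). Rassf2, a Ras-binding protein gene, had the smallest adjusted p (2.12 ± 0.243, adjusted p = 0.192), and the hyaluronan synthase gene Has2 and the calcineurin regulator gene Rcan2 stood at -1.12 ± 0.244 (adjusted p = 0.976) and -1.28 ± 0.229 (adjusted p = 0.74). No gene passed edgeR's quasi-likelihood test, with 301 at an unadjusted p under 0.05, fewer than the 634 expected by chance. The fit shared its spread with p62KO libraries, whose replicates differed more (chi-squared per degree of freedom 61 and 200, against 1.66 and 12.2 in WT). The test was therefore strict for WT cells, and the lack of passing genes does not show that they did not respond.

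DESeq2 called 16 genes in WT cells, 14 higher and 2 lower, among them Cyp24a1, Rassf2, Afap1l2, Moxd1 and Cib2 (higher) and Rcan2 and Has2 (lower). Without the filter edgeR called Cyp24a1, Afap1l2 and Rassf2. A fit of only the 2 groups called 345 genes, and the fit without the 2 p62KO libraries that stood apart called 283. Camera called 10 of 27 lists, among them vitamin D receptor targets as higher (median 0.49; 3 of 12 rose when adjusted over the list alone) and MYC targets and the cell cycle as lower (medians -0.22 and -0.12), though no member passed. None of the 10 held with an estimated correlation (adjusted p from 0.548 to 0.813), and none was called without WT calcipotriol replicate 1, where the macrophage marker list stood at 1.52 against 0.10 in replicate 2. Without WT vehicle replicate 2 or without p62KO calcipotriol replicate 1, 6 were called, among them vitamin D receptor targets.

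In p62KO cells, Cyp24a1 stood at 28.4 ± 6.35 CPM (SD, n = 2) with calcipotriol and 3.47 ± 2.33 CPM with vehicle, a log2 fold change of 3.03 ± 0.427 (SE, adjusted p = 0.303). Vdr stood at 22.8 ± 4.55 CPM against 12.8 ± 3.74 CPM (0.83 ± 0.252, adjusted p = 0.361). Rassf2 had a log2 fold change of 2.49 ± 0.244 (adjusted p = 0.0555) and Afap1l2 of 2.03 ± 0.249 (adjusted p = 0.165). Inmt, a methyltransferase gene, was at least 28.3-fold higher, with no counts in vehicle-treated p62KO cells. No gene passed edgeR's quasi-likelihood test, with 1714 at an unadjusted p under 0.05 against 634 expected by chance, and DESeq2 called 53, of which 34 were higher and 19 lower; 7 of the 53 were also among the 16 in WT cells.

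The count in p62KO cells rested on single libraries: 4559 genes passed without calcipotriol replicate 1, where the lone remaining library was the one with the lowest X chromosome median, and 195 passed without vehicle replicate 2. Without the filter 6 passed, Cyp24a1, Rassf2, Afap1l2, Inmt, Apcdd1 and Krt17, and without both libraries that stood apart 5 passed, Cyp24a1, Rassf2, Apcdd1, Mmp3 and Fam43a. Krt17, Mmp3 and Fam43a are named here after their values were seen. Camera called 3 lists as lower, cholesterol synthesis (median -0.59), inflammatory genes (-0.90) and markers of liver tumours and progenitors (-0.48), with no member past the threshold and an adjusted p of 0.846 with an estimated correlation. None of the 3 was called without p62KO vehicle replicate 1, or without p62KO calcipotriol replicate 1. Without p62KO vehicle replicate 2 there were 11 called lists and without p62KO calcipotriol replicate 2 there were 7, the 3 included.

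The interaction asked whether calcipotriol acted differently without p62. For Cyp24a1 the difference between the responses was -0.01 ± 0.642 (log2, SE, adjusted p = 0.997), and for Vdr -0.14 ± 0.356 (adjusted p = 0.895). Comparing p62KO with WT, the log2 fold change of Cyp24a1 was -1.40 ± 0.422 among vehicle-treated cells (edgeR, adjusted p = 0.0633), which did not pass. Among calcipotriol-treated cells it was -1.41 ± 0.385 (edgeR, adjusted p = 0.0366), lower in p62KO. That call did not hold in every fit with a library left out. Of 12 tested vitamin D receptor targets, 4 fell and 1 rose in p62KO against WT with calcipotriol (median -0.78). With vehicle 3 fell and 2 rose (median -0.46). Camera did not call the list as lower (adjusted p = 0.073 with calcipotriol and 0.31 with vehicle). Fry did (adjusted p = 0.0103 and 0.0336). Cyp1a1, a target of the aryl hydrocarbon receptor, stood at 0.270 and 1.27 CPM in WT cells with vehicle and calcipotriol and at 7.59 and 3.93 CPM in p62KO cells (difference -3.15 ± 0.614, adjusted p = 0.708). No gene passed edgeR's quasi-likelihood test, with 677 at an unadjusted p under 0.05 against 634 expected by chance, and DESeq2 called 0. Without p62KO calcipotriol replicate 1, 2514 genes passed, and without p62KO vehicle replicate 2, 7 did.

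Camera called 10 of 27 lists in the interaction, with no member of any past the threshold. MYC targets and collagens and matrix responded more positively in p62KO (medians 0.52 and 0.31), and cholesterol synthesis (-0.79) and 7 other lists more negatively. None held with an estimated correlation (adjusted p from 0.58 to 0.781). Without p62KO calcipotriol replicate 1 none was called. Without p62KO vehicle replicate 1 the lists of MYC targets, bile acid and xenobiotic genes and interferon response were called, and without both libraries that stood apart MYC targets and interferon response were. The number called was 6 without WT vehicle replicate 2, 5 without WT calcipotriol replicate 1 and 16 without p62KO vehicle replicate 2. Col1a1, the other chain of type I collagen, did not pass in the interaction (0.84 ± 0.38, adjusted p = 0.708) and is named here after its values were seen. It stood at 2256 and 2325 CPM in vehicle-treated and 2279 and 2693 CPM in calcipotriol-treated WT libraries, and at 3061 and 3385 CPM and 4478 and 8028 CPM in the p62KO libraries.

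Liver and vehicle-treated stellate cells shared more genes raised in p62KO than chance gives. Of 11218 genes tested in both, 61 were higher in both against 31 expected (odds ratio 2.21, 95% interval 1.64 to 2.93, Fisher's exact p = 3.12e-07), among them Col1a2, Pmepa1 and Cd34. Only 7 were lower in both against 18.9 expected (odds ratio 0.351, Fisher's exact p = 0.00239), Sqstm1 among them. Genes higher in liver and lower in stellate cells numbered 42 against 26.3 expected (odds ratio 1.7, Fisher's exact p = 0.00275), among them Sparc, Spp1 and Lpl, and genes lower in liver and higher in stellate cells 30 against 22.2 (Fisher's exact p = 0.0938; with a stricter filter 29 against 16, p = 0.00155, and without a filter 37 against 24.1, p = 0.00993). Genes are not independent of each other, so these p-values are too small by an unknown amount. Differences between the cell lines enter these overlaps as well.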

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

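The test of genes near Sqstm1 was chosen only after the result it measures was seen, as were the list tests with libraries left out, whereas the comparisons between the treatments, genotypes and tissues were planned.

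By the camera test of the interaction with a preset correlation, 10 gene lists were called as responding differently to calcipotriol in p62KO and WT stellate cells (adjusted p between 1.81e-04 and 0.0358), and none with an estimated correlation (adjusted p between 0.58 and 0.781). The median difference (p62KO response less WT response, log2) was 0.52 for MYC targets and 0.31 for collagens and matrix. It was -0.79 for cholesterol synthesis, -0.55 for PPAR-alpha and fatty acid oxidation, and -0.90 for inflammatory cytokines and NF-kB targets. For autophagy and lysosome genes it was -0.45, for p53 targets -0.55 and for interferon response -0.87. The lists with the largest medians had few tested members, macrophage markers 5 (-2.06) and bile acid and xenobiotic genes 6 (-2.44). Of the macrophage markers, Csf1r stood at 5.85 and 0.792 CPM and Gpnmb at 156 and 23.9 CPM in p62KO vehicle replicates 1 and 2. In WT calcipotriol replicates 1 and 2, Csf1r stood at 1.84 and 1.03 CPM and Gpnmb at 184 and 60.1 CPM. High values in either of these groups make the interaction more negative. No gene passed in the interaction (edgeR, 677 at an unadjusted p under 0.05, DESeq2 0), and the number of called lists was 0 without p62KO calcipotriol replicate 1, 3 without p62KO vehicle replicate 1, 5 without WT calcipotriol replicate 1, 6 without WT vehicle replicate 2 and 16 without p62KO vehicle replicate 2.

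Of the genes reported by name, 9 passed in both vehicle-treated p62KO stellate cells and p62KO liver with opposite signs, and the difference between the tissues was not tested. Higher in stellate cells and lower in liver were Herpud1, a gene of protein quality control in the endoplasmic reticulum (log2 fold change 1.30 and -0.87), Nqo1, a quinone reductase and NRF2 target (2.06 and -1.07), the clock repressor Gm129 (1.29 and -1.10) and Pttg1 (2.29 and -3.23). Lower in stellate cells and higher in liver were Spp1 (-2.41 and 2.24), Sparc (-1.04 and 2.08), the lipoprotein lipase gene Lpl (-2.54 and 1.42), the kinase gene Plk2 (-0.76 and 1.14) and the adaptor gene Shc2 (-2.02 and 3.15).

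Pttg1 lies near Sqstm1 on chromosome 11, and genes around the knocked-out locus can differ between strains when a segment of chromosome stays linked to it. Of 192 genes within 15 Mb of Sqstm1, 24 passed in p62KO liver (12.5%), against 986 of 12534 elsewhere (7.87%; odds ratio 1.67, Fisher's exact p = 0.0298). Windows of 5, 10, 20 and 30 Mb gave Fisher's exact p of 0.836, 0.0419, 0.00962 and 0.138. Over the 5 windows the adjusted p was 0.0698 at 15 Mb and 0.0481 at 20 Mb. In vehicle-treated stellate cells the odds ratio was below 1 in every window (0.731 at 15 Mb, adjusted p = 0.39). At 30 Mb genes near Sqstm1 passed less often there than others (odds ratio 0.578, Fisher's exact p = 0.000865, adjusted p = 0.00432). Of all 1019 tested genes on chromosome 11, 7.95% passed in these cells, against 9.84% of those within 15 Mb of Sqstm1. The low odds ratios thus do not set the locus apart from the rest of its chromosome. Of the 24 genes that passed near Sqstm1 in liver, 22 were also tested in stellate cells. There 11 went the same way, among them 2610507I01Rik (-5.11 in liver and -5.00 in stellate cells) and Lyrm7 (-1.88 and -1.72). The opposite way went 11, among them Pttg1 and the matrix gene Sparc (2.08 in liver and -1.04 in stellate cells). Both 2610507I01Rik and Lyrm7 are named here after their values were seen. Of the 10 genes with the smallest p besides Sqstm1, 4 lay within 15 Mb in liver and 0 in vehicle-treated stellate cells. A linked segment may therefore account for a part of these genes, but these values leave it open, and neither the strain of the animals nor a direct effect of p62 was tested.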

How the results depend on the processing

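The fits without both stellate cell libraries that stood apart, those with chromosome medians removed, the exchanged replicate numbers and the list tests with libraries left out were chosen only after seeing the data. In liver the count of 1020 genes became 2442 with DESeq2, 639 with the replicate block and 462 at a minimum of 2-fold, and ranged from 3 to 3669 with a library left out. In vehicle-treated p62KO stellate cells the count of 1634 became 5459 without both libraries that stood apart and 1002 with chromosome medians removed, and ranged from 238 to 3635 with a library left out. With calcipotriol the count of 2509 became 1644 at a minimum of 2-fold, 1293 with only the 2 groups, 5606 without both libraries that stood apart and 1417 with chromosome medians removed, and ranged from 272 to 6052. For calcipotriol in WT cells the count of 0 became 16 with DESeq2, 3 without the filter, 345 with only the 2 groups and 283 without both libraries that stood apart, and stayed at 0 with each library left out. In p62KO cells the count of 0 became 53 with DESeq2, 6 without the filter and 5 without both libraries that stood apart, and ranged from 0 to 4559. For the interaction it ranged from 0 to 2514. The other alternatives gave counts within 1.5 times the reported one. At an unadjusted p under 0.01, 111 genes were higher and 12 lower in both liver and stellate cells. With an estimated correlation, a run that rests on few degrees of freedom, camera called 0 lists in each of the 6 comparisons. Fry called 13 lists in liver (12 shared), 8 in vehicle-treated p62KO cells (3 shared), 8 in calcipotriol-treated p62KO cells (2 shared) and 0 in the other comparisons. With a library left out, camera called 16 to 19 lists in liver, 3 to 11 in vehicle-treated and 1 to 7 in calcipotriol-treated p62KO cells, 0 to 10 for calcipotriol in WT and 0 to 11 in p62KO cells, and 0 to 16 in the interaction. Without both libraries that stood apart these were 3, 4, 8, 1 and 2 in stellate cells, and with chromosome medians removed 7, 4, 10, 6 and 10, in the same order. No named gene changed sign under an alternative where it passed in the reported test or in that alternative. Sign changes of values that passed in neither were not counted. Of the named genes' values under the alternatives, 309 in liver, 169 in vehicle-treated and 186 in calcipotriol-treated p62KO cells no longer passed. The cause of these changes was not tested, except that a fit with a library left out rests on fewer samples. Genes changed 2-fold were mostly missed in the simulated data, with 42 of 100 recovered in liver and 15 of 100 in vehicle-treated p62KO cells.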

Other observations

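Chosen only after the results were seen were the gene families and the tests of chromosome 10 segments, of chromosome 10 in liver and of the X chromosome. The same holds for the test of the share of hepatocytes and the fits with chromosome medians removed. The splits of the livers were planned. The limits for the test of GC content and length were set before it was run, but for a chromosome picked from its values.

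Some nuclear genes for the mitochondrial respiratory chain fell in p62KO livers. Among 25 families picked by symbol, 23 of which had enough genes in liver and 20 in stellate cells, the subunits of complex I (Nduf) had a median of -0.62 in liver, where 19 of 37 fell and none rose (adjusted p = 0.375 with an estimated correlation). Ndufa3, named here after its values were seen, fell from 67.9 ± 2.26 to 38.3 ± 5.16 CPM (SD, n = 3 each). Subunits of complex IV fell in 6 of 12 cases (median -0.69), of ATP synthase in 7 of 15 (-0.59), of complex III in 3 of 8 (-0.61) and mitochondrial ribosomal proteins in 20 of 76 (-0.37). Cytosolic ribosomal proteins had a median of 0.04, with 0 of 73 passing. The shift was not limited to mitochondrial genes: proteasome subunits had a median of -0.34, with 33 of 38 below 0 and 0 passing. In vehicle-treated p62KO stellate cells 7 of 36 complex I genes rose and none fell (median 0.46; adjusted p = 0.38 with an estimated correlation), and 2 of 13 complex IV genes rose (0.44). Of complex III 0 of 8 passed there (0.47), and of ATP synthase 1 of 15 fell and none rose (0.13). The difference between liver and stellate cells was not tested.

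In p62KO livers, of the cytochrome P450 family 2, 8 of 35 fell (median -0.77), and of the glutathione S-transferases 6 of 18 (-0.88), with an adjusted p of 0.375 for both with an estimated correlation. Hamp2, a gene of the hepcidin family distinct from Hamp, fell from 38.4 to 3.32 CPM, and Itih5 rose from 13.7 to 111 CPM. In vehicle-treated p62KO stellate cells 4 of 11 genes of the H2 antigen-presentation locus rose and none fell (median 1.19; adjusted p = 0.38 with an estimated correlation).

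The number of genes that differed between p62KO and WT livers was compared with that from other splits of the 6 livers. The real split gave 1020 genes and the highest of the others gave 1, so 1 of 10 splits gave as many as the real one. With 10 splits a share under 0.05 cannot be reached.

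In vehicle-treated p62KO stellate cells the genes of chromosome 10 had the most extreme median apart from the 4 tested genes of Y (-0.98). The chromosome was picked for that. A one-sided permutation test gave p = 1e-04, the smallest that 10000 permutations can give. That p is too small for a chromosome picked in this way. GC content and length are argued against as the cause, since the chromosome 10 median was -0.65 before and -0.79 after a trend on them was removed, among the 93.9% of genes with a value. A loss of p62 that acts alike in liver and stellate cells is argued against by the liver median of 0.013, and calcipotriol as the source of the low X chromosome in p62KO calcipotriol replicate 2 by the X median of replicate 1, -0.137 against -0.631 relative to vehicle-treated p62KO cells. All of 10 segments along chromosome 10 had a median below the limit set, from -0.839 to -0.452, which is consistent with a different copy number in the cell lines, a candidate explanation that needs DNA data, which were not used here. With chromosome medians removed, 1002 genes passed in vehicle-treated cells, 895 of them shared with the 1634.

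The median changes of markers of macrophages, cholangiocytes and matrix-producing cells were above 0 in p62KO livers and that of hepatocyte genes was below 0, which a lower share of hepatocytes could give. Such a drop raises the markers of all other cell types alike, as far as hepatocytes do not express them, which was not tested. The medians were 1.32 for collagens and matrix, 1.76 for cholangiocytes and 0.99 for macrophages. They were 0.78 for T and NK cells, 0.33 for endothelial cells and 0.24 for quiescent stellate cells. The matrix median less the endothelial median was 0.94 ± 0.3 in p62KO and 0 ± 0.15 in WT livers (SD, n = 3 each), a difference of 0.94 for a pair of lists picked after their values were seen. As far as hepatocytes do not express these markers, a lower share of hepatocytes alone is argued against as the whole cause. More matrix-producing cells, or more matrix expression per cell, stay open and were not tested.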
